A study of Mus musculus with 52 samples.

How the data were processed

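RNA of 52 mouse libraries was analysed from gene tables that the authors deposited, 20 libraries of haematopoietic stem cells (HSC) and 32 of bone marrow stroma. HSC were sorted by flow cytometry as lineage-negative cells with the SLAM marker profile, per the labels' protocols. Stroma was enriched with magnetic beads for cells negative for CD45 and Ter119. Per the labels' protocols, HSC libraries came from 1 ng of RNA with a RIN above 7, made with SMART-Seq v4 and Nextera XT. Stroma libraries came from 100 ng of RNA with a RIN above 8, made with KAPA mRNA HyperPrep. Both were sequenced in pairs of 100 bp reads on a NovaSeq sequencer. The strand setting of the read counting is not given in the sources used here, so reads of overlapping genes and of antisense partners cannot be told apart, and genes that share sequence with a close copy are equally uncertain.

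The authors' steps before deposit are taken from the submitters' processing notes. These name FastQC 0.11.5, STAR 2.5, featureCounts of Subread 1.5.1, edgeR 3.36.0 and the mouse genome build mm10. The values analysed are the raw counts per gene and library, which the authors deposited with no normalisation, per the file headers. The authors also deposited log2 fold changes and their FDR, an adjusted p-value, for their own comparisons, per the file headers. These serve only for the side-by-side reading named as the authors' deposited table. The 52 columns of log2 CPM per library were not used. Gene coordinates are those of the authors' file in mm10. The deposited tables held 13566 genes for HSC and 15168 for stroma, and no further gene was removed here. The lowest total over the libraries of a cell fraction was 84 counts in HSC and 148 in stroma, so the usual filter on low counts removed 0 genes.

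Each group held 4 mice, 2 male and 2 female, with 1 library per mouse, grouped by the labels. The HSC groups were vehicle, sulprostone, rivenprost, both agonists and misoprostol, all irradiated. The stroma groups were those 5, dmPGE2 with irradiation, and vehicle and dmPGE2 without irradiation. The comparisons with a control were each treatment against irradiated vehicle, irradiated against non-irradiated vehicle, and dmPGE2 against vehicle in non-irradiated mice. Direct comparisons between compounds, the departure from additivity of the 2 agonists (the change with both, less the sum of the changes with each) and the interaction of dmPGE2 with irradiation were tested as well. Tests, covariates, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined.

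Counts were tested with edgeR 4.0.16 under R 4.3.3, by the quasi-likelihood test with robust prior and TMM factors. One model per cell fraction held a term for every group and a term for sex, so that all groups of a fraction shared an estimate of the spread. It left 14 residual degrees of freedom in HSC and 23 in stroma, with prior degrees of freedom of 5.61 and 3.51 and a common biological coefficient of variation of 0.781 and 0.302. Every adjusted p is Benjamini-Hochberg adjusted over the genes of a comparison unless said otherwise, and a gene counts as changed at an adjusted p under 0.05. These p-values measure the spread between mice. Values in CPM are counts scaled to the TMM-adjusted library size, as mean ± SD over the 4 mice, and logarithms of CPM used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 at the preset correlation of 0.01, and again with a correlation estimated from the data, whose p is the one printed. Of 858 list tests 294 passed at the preset correlation and 19 with an estimated one. Library composition between groups was tested by exact two-sided permutation over the 70 relabellings of 4 and 4 mice, where the smallest possible p is 0.0286. Such p occurred in 46 of 385 tests, and the smallest adjusted value was 0.239. DESeq2 1.42.0 served as an alternative.

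The 34 fixed lists held 838 symbols, of which 679 had a measured gene in HSC and 784 in stroma. They were p53 targets, cAMP-CREB response genes, immediate early genes, NF-kB and inflammatory cytokine genes, interferon-stimulated genes, prostaglandin receptor and metabolism genes, HSC markers, HSC quiescence genes, mitotic genes, S-phase genes, DNA repair and damage signalling genes, anti-apoptotic and pro-apoptotic BCL2-IAP genes, hypoxia response genes, NRF2 antioxidant genes, glucocorticoid response genes, heat shock genes, Wnt target genes and niche factor genes. Markers of cell types were listed for mesenchymal CAR-cells, the osteoblast lineage, endothelium, pericytes and smooth muscle, fibroblasts and chondrocytes, erythroid cells, granulocytes, monocytes and macrophages, B cells, plasma cells, T and NK cells, megakaryocytes and platelets, and mast cells and basophils. The remaining lists were lineage-primed progenitor genes, cytosolic ribosomal protein genes and mitochondrially encoded genes. No mitochondrially encoded gene is in the tables, so 33 lists were tested. Some genes belong to several lists, as Cdkn1a, Lif and Nr4a1 do. Counts per list are given over all genes tested and adjusted over the list alone. The list medians printed do not change when genes with 0 counts in a whole group are set at their bound.

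Genes were named by a fixed rule. In each comparison with a control these were up to 8 rising and 8 falling genes with the largest log2 fold change among those with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the values of the 4 and 4 libraries, leaving out numbered gene models. To these the rule added, for each list with at least 3 changed members, the 3 with the smallest p, or the 5 genes with the smallest p where fewer than 5 genes changed, and the levels of Ptger1, Ptger2, Ptger3 and Ptger4. Direct comparisons and interactions allowed up to 5 and 5 genes, or the 3 with the smallest p, and any gene already allowed for that cell fraction. Xist, Kdm5d and Eif2s3y, with Ddx3y and Uty, checked the sex labels. This gave 318 pairs of a gene and a comparison. Those printed are a subset of them, picked after their values and the results with each library left out had been seen, with preference for calls that held. Some genes that met the rule are not reported here. Of 288 such pairs past the test 181 held with each library left out in turn. Genes outside the rule are named only as chosen after their values were seen.

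The depth was 27.4 to 49.2 M counts per HSC library and 38.0 to 73.7 M per stroma library. The gene with most counts took 0.431 to 1.04% of a library in HSC and 1.76 to 4.87% in stroma. A count of 0 in a whole group was read as at most 3 counts over the group, and folds against it are lower bounds on that floor. Intervals and floors of this kind cover counting error only, while intervals of 95% on log2 fold changes come from the edgeR model. Pairs of libraries were checked for duplicates, over 30 pairs in HSC and 48 in stroma, and none was found.

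The steps were tested on simulated counts with the libraries' own depths, means and spread, with 200 genes changed in each simulated comparison. For rivenprost against vehicle in HSC (13566 genes), 2 of 68 genes changed by 0.5 on the log2 scale were recovered, 17 of 66 changed by 1 and 39 of 66 changed by 2, with 2 false calls among 13366 unchanged genes. For dmPGE2 against vehicle in irradiated stroma (15168 genes) these were 8 of 68, 31 of 66 and 51 of 66, with 1 false call among 14968 genes. Every recovered gene had the right direction. Comparisons with shared controls were set against 100 simulations of unchanged groups, of which 10 held calls.

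Alternatives tried were RLE size factors, the Wald test of DESeq2, no filter, a stricter filter (CPM of at least 1 in at least 4 libraries), no sex term, the run of consecutive animal numbers as a block, a fit of only the groups compared, each library left out in turn, a minimum log2 fold change of 1, genes of at least 5 CPM for correlations, the estimated correlation of list tests and vehicle libraries split between comparisons. Added after seeing the data were the position of an animal within its number run as a covariate in HSC, a fit without 3 HSC libraries that stood apart, a fit without the later-numbered replicate 4 of both non-irradiated groups, the leave-one-out fits of the sex difference, and the split of vehicle libraries for genes shared between comparisons. For the interactions, other groupings of the libraries were first drawn 30 times and then 100 times, after the first result was seen. A few counts are given as their rising and falling parts, as a share or to 2 digits, because the same whole numbers serve as column numbers in the analysis.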

Results

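RNA was sequenced from 2 bone marrow fractions of mice given a prostaglandin E receptor agonist, or vehicle, by injection 30 min before total-body irradiation with 853 cGy, with marrow taken 1 h after irradiation. The first fraction was haematopoietic stem cells (HSC), sorted by surface markers, and the second was the stroma, enriched with magnets for cells without the blood-cell markers CD45 and Ter119. The agonists were sulprostone for the receptor EP3, rivenprost for EP4, both together, and misoprostol. Stroma was also taken after dmPGE2, a stable analogue of prostaglandin E2, and from non-irradiated mice given vehicle or dmPGE2. The labels write PGE, read here as dmPGE2 from the series title. The design text mentions vehicle alone for non-irradiated mice, and the labels were followed. The doses of the agonists were not given in the sources used here, so compounds are compared at unknown relative doses. Each of the 13 groups held 4 mice, 2 male and 2 female, with 1 library each. Values are means ± SD over these mice unless said otherwise. Median depth was 40.8 M counts in HSC and 55.6 M in stroma.

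The sex labels were checked first. Xist, expressed from the inactive X chromosome, had 3789 to 7934 counts in female and at most 31 in male HSC libraries, and the Y-linked genes Kdm5d and Eif2s3y had 0 counts in female HSC. In stroma, females had 161 to 19965 counts of Xist and males at most 17. The receptor genes were also read as levels. HSC of irradiated vehicle mice held Ptger3 at 116.6 ± 40.7 and Ptger4 at 80.96 ± 22.3 CPM (counts scaled to library size), Ptger1 at 7.21 ± 5.85 and Ptger2 at 0.320 ± 0.640. Irradiated vehicle stroma held Ptger4 at 25.2 ± 5.43, Ptger3 at 6.38 ± 1.31, Ptger2 at 2.58 ± 0.439 and Ptger1 at 0.409 ± 0.150 CPM. Ptger2 was the only receptor gene past the test in any comparison with a control, at 0.721 ± 0.350 CPM after dmPGE2 without irradiation against 2.24 ± 0.671 (log2 fold change -1.64, adjusted p = 0.0491). That call ended without non-irradiated dmPGE2 replicate 1, 2 or 3 (adjusted p = 0.159, 0.0531 and 0.160) and without non-irradiated vehicle replicate 1, 3 or 4 (0.0789, 0.157 and 0.0897). It also ended in a fit of these 2 groups alone.

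The comparison of rivenprost with vehicle asked which genes an EP4 agonist changed in stem cells of irradiated mice. After rivenprost, Crem, a cAMP-responsive transcriptional modulator (mm10 chromosome 18, 3266354 to 3337589), stood at 197 ± 28.5 CPM against 7.24 ± 2.03 CPM in irradiated vehicle HSC, a log2 fold change of 4.81 (SE 0.32, adjusted p = 4.05e-08). Hk2, a hexokinase of glycolysis (chromosome 6, 82725027 to 82774454), rose from 29.0 ± 4.26 to 167 ± 41.7 CPM (log2 fold change 2.52, SE 0.22, adjusted p = 1.25e-06). Plaur, the urokinase receptor gene (chromosome 7, 24462500 to 24475873), rose from 19.1 ± 5.93 to 211 ± 64.6 CPM (3.51, SE 0.33, adjusted p = 4.45e-06). The nuclear receptor gene Nr4a1 rose by 3.70 on the log2 scale, the transcription factor gene Cebpb by 2.86, and Socs3, an inhibitor of cytokine signalling, by 4.16. Lmcd1 (3.72), the phosphatase gene Dusp5 (2.09), Egln3 (2.16), Fosl2 (1.90) and the cAMP phosphodiesterase gene Pde4b (1.41) rose as well, while Gimap6 fell (-1.10, SE 0.17, adjusted p = 0.00146). Ramp3, an accessory protein of calcitonin-family receptors, had 0 counts in vehicle HSC and 93.4 ± 10.9 CPM after rivenprost, at least 4930-fold higher when 3 counts over the vehicle group are taken as the limit. Pdcd1, an inhibitory immune receptor gene, had 13 counts in 1 vehicle library and 26.4 ± 5.99 CPM after rivenprost (adjusted p = 4.62e-05).

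Of the cAMP-CREB response genes, 9 of 33 measured members rose and 1 fell in HSC after rivenprost (13 and 2 adjusted over the list alone), with a median log2 fold change of 1.05 (adjusted p = 0.00022 with an estimated correlation). Crem, Nr4a1 and Pde4b were among those that rose. Of the immediate early genes 4 of 29 rose (11 rose and 1 fell adjusted over the list alone, median 0.73, adjusted p = 0.027 with an estimated correlation). Among the hypoxia response genes 3 of 29 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.14 and adjusted p = 0.027 with an estimated correlation, and Hk2 and Egln3 were among the members that rose. For the p53 targets 0 of 45 passed the test over all genes (2 rose and 6 fell adjusted over the list alone, median -0.33, adjusted p = 0.075 with an estimated correlation). Rivenprost changed 67 genes in HSC, 54 rising and 13 falling, and 36 of them were called with each library left out in turn. The count was 41 without rivenprost replicate 3 or vehicle replicate 3, and 42 without rivenprost replicate 4.

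With sulprostone and rivenprost together, HSC held Crem at 188 ± 89.5 CPM (log2 fold change 4.70, SE 0.32, adjusted p = 5.6e-08), Hk2 at 163 ± 17.4 CPM (2.49, SE 0.21, adjusted p = 1.5e-06) and Plaur at 277 ± 59.7 CPM (3.87, SE 0.34, adjusted p = 1.5e-06). Fos, a subunit of the transcription factor AP-1, rose from 14 ± 8.98 to 306 ± 109 CPM (4.49, SE 0.51, adjusted p = 3.33e-05), and Socs3 to 240 ± 27.2 CPM (5.31). Nr4a1 (3.53), Dusp1 (2.33), Egln3 (2.22) and Sgk1 (1.89) also rose. Among falling genes were Rsrp1 at 42.9 CPM against 399 ± 219, Trp53inp1, a p53-induced stress gene, at 50.1 ± 24.4 CPM against 211 ± 19.5 (-2.12, SE 0.35, adjusted p = 0.003), Cited2 (-1.78) and Txnip, an inhibitor of thioredoxin (-1.20). Ramp3 reached 89.2 ± 70.9 CPM, at least 4700-fold higher than in vehicle HSC, and Pdcd1 31.6 ± 16.1 CPM. Jun (-1.58) and Icam1 (-1.86) passed the test (adjusted p = 0.00385 and 0.00724) but not in a fit of these 2 groups alone (adjusted p = 0.073 and 0.0591).

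In the same comparison 9 of 33 cAMP-CREB response genes rose and 1 fell (15 and 2 adjusted over the list alone, median 0.92, adjusted p = 0.00023 with an estimated correlation). Of 29 immediate early genes 9 rose and 2 fell (14 and 3 adjusted over the list alone, median 0.79, adjusted p = 0.025 with an estimated correlation), with Fos rising and Jun falling. None of the 45 p53 targets rose and 4 fell (1 and 11 adjusted over the list alone, median -0.33, adjusted p = 0.022 with an estimated correlation). Of 34 NF-kB and inflammatory cytokine genes 3 rose and 1 fell (8 and 2 adjusted over the list alone), with a median of -0.07 but a mean of 0.96, and adjusted p = 0.66 with an estimated correlation. Granulocyte markers had a median of -1.01 and monocyte and macrophage markers of -0.72 (adjusted p = 0.98 and 0.76 with an estimated correlation). Both agonists changed 74 genes, 55 rising and 19 falling, of which 41 were called with each library left out in turn. The count was 49 without vehicle replicate 3 and 43 in a fit of these 2 groups alone.

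The same genes were read after misoprostol. Crem stood at 84.5 ± 30.8 CPM (log2 fold change 3.52, SE 0.30, adjusted p = 3.62e-06), Hk2 at 140 ± 32.1 CPM (2.27, SE 0.21, adjusted p = 9.01e-06), and Socs3 at 147 ± 96.1 CPM (4.56, SE 0.54, adjusted p = 0.000146), and Plaur rose by 2.70 (SE 0.32, adjusted p = 0.000146). Fos rose to 120 ± 43.9 CPM (3.10), and Ramp3 was at 21.4 ± 5.90 CPM, at least 1130-fold higher than in vehicle HSC. Nr4a1 (2.83), Rasd1 (2.86), Fosl2 (1.94), Gimap6 (-1.05) and Pdcd1 (16.2 ± 7.89 CPM) passed the test in the fit of all HSC groups, and not in a fit of these 2 groups alone (adjusted p = 0.0916, 0.0515, 0.0973, 0.0973 and 0.156). Of the cAMP-CREB response genes 5 of 33 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.71, adjusted p = 0.0037 with an estimated correlation). Of the immediate early genes 6 of 29 rose (11 rose and 2 fell adjusted over the list alone, median 0.53, adjusted p = 0.071 with an estimated correlation), and 1 of 45 p53 targets fell (3 adjusted over the list alone, median -0.32, adjusted p = 0.076 with an estimated correlation). Misoprostol changed 34 genes, 30 rising and 4 falling, with 19 without misoprostol replicate 1, 18 and 40 without vehicle replicate 3 and 2, 235 by DESeq2 and 9 in the fit of these 2 groups alone.

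Sulprostone alone changed 2 genes in HSC by edgeR. Crem rose to 32 ± 12.7 CPM (log2 fold change 2.10, SE 0.29, adjusted p = 0.00399), and Pdcd1 stood at 7.4 ± 4.32 CPM against 13 counts in 1 vehicle library (adjusted p = 0.00399). Both calls held with each library left out in turn. Neither call held without the 3 HSC libraries that stood apart in composition, sulprostone replicate 1, vehicle replicate 2 and misoprostol replicate 2 (adjusted p = 0.0706 for each) or in a fit of these 2 groups alone (adjusted p = 1 for each), while the log2 fold change of Crem stayed at 2.04 and 2.09. Of the cAMP-CREB response genes 1 of 33 rose (5 adjusted over the list alone, median 0.27, adjusted p = 0.055 with an estimated correlation). At an unadjusted p under 0.05 there were 611 of 13566 genes, below the share of 0.05 expected without any effect. DESeq2 called 103. Markers of mature blood cells stood higher in sulprostone HSC, with medians of 3.61 for granulocyte, 1.95 for erythroid, 1.68 for B-cell and 0.97 for monocyte and macrophage markers (adjusted p = 0.76, 0.61, 0.84 and 0.83 with an estimated correlation). This rested on sulprostone replicate 1. Among genes chosen after their values were seen, it held the neutrophil genes S100a8 at 3780 and S100a9 at 3070 CPM, against at most 41.9 and 32.1 CPM in any other HSC library, and the haem synthesis gene Alas2 at 3640 against at most 231 CPM.

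**Figure D1:**
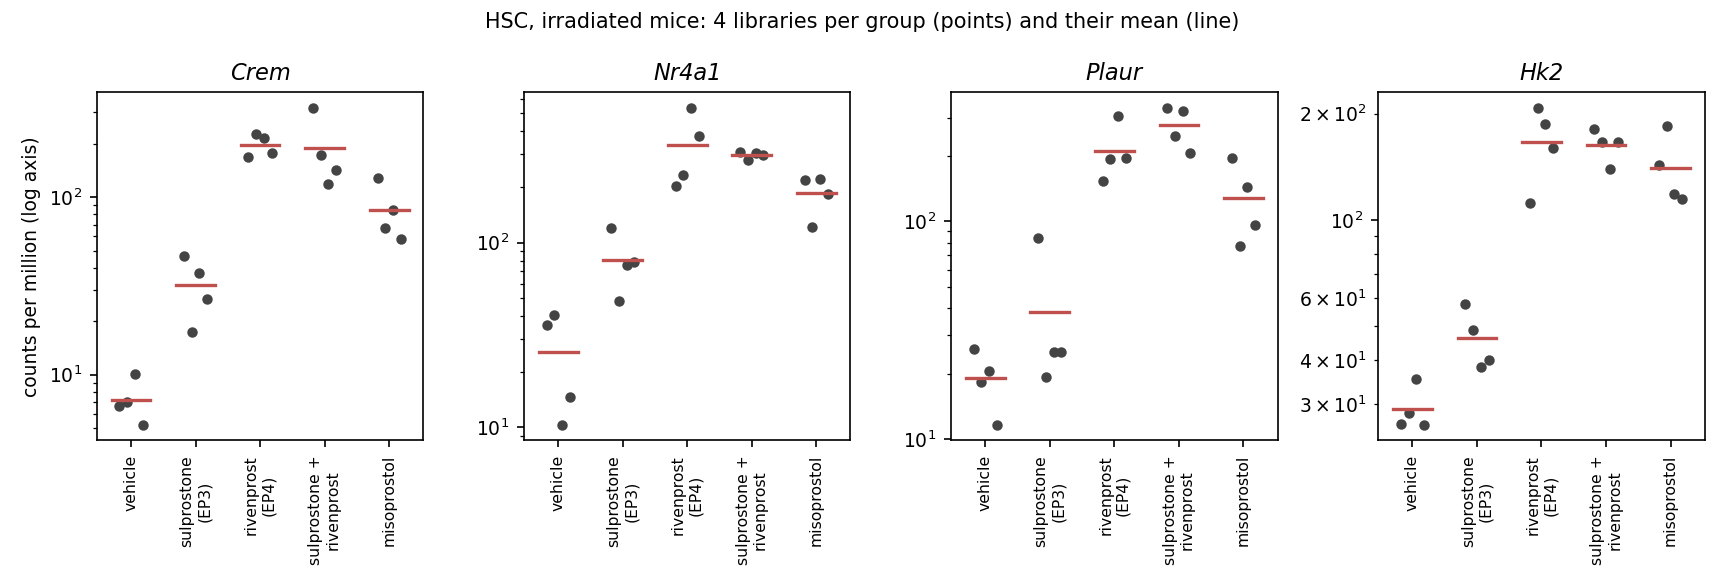
Expression of Crem, Nr4a1, Plaur and Hk2 in each HSC library (CPM, log axis) by treatment of irradiated mice, with 1 point per mouse and the group mean. Crem averaged 7.24 CPM after vehicle, 32 after sulprostone, 197 after rivenprost, 188 after both agonists and 84.5 after misoprostol.

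**Figure D2:**
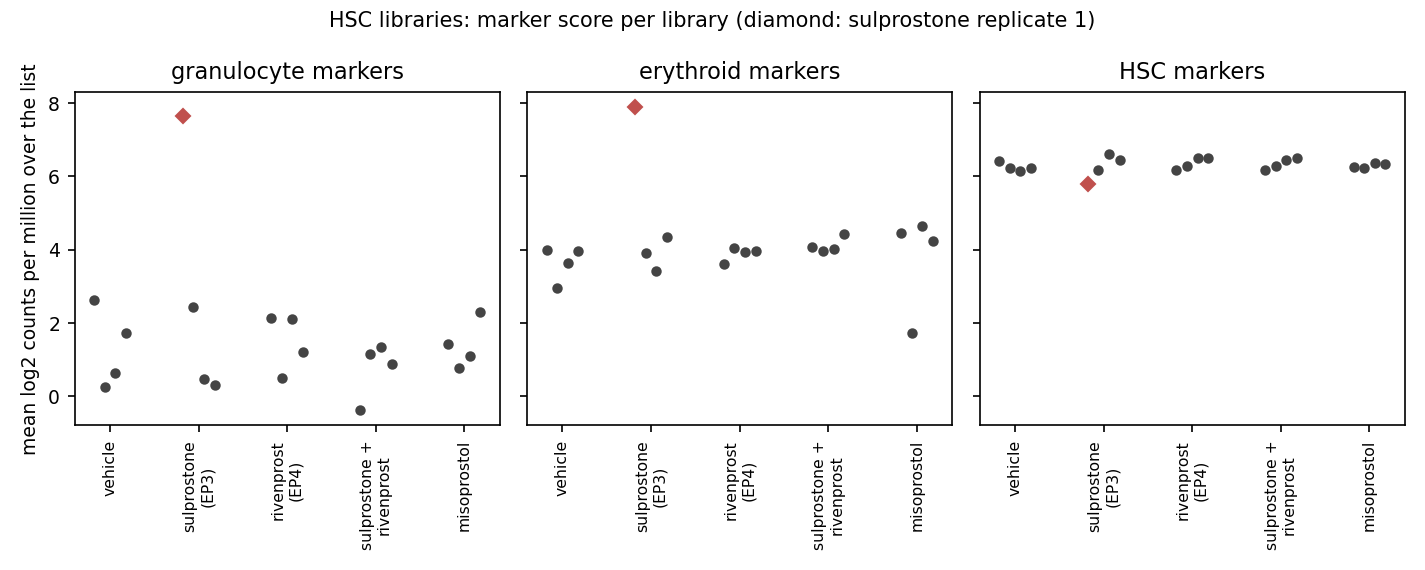
Mean log2 CPM of granulocyte, erythroid and HSC marker genes in each HSC library by treatment, with a diamond for sulprostone replicate 1. Its granulocyte score was 7.64 against -0.38 to 2.63 in the other libraries, and its HSC marker score 5.79 against 6.16 to 6.62.

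The compounds were then compared directly in HSC. Crem was 2.71 log2 units higher after rivenprost than after sulprostone (95% interval 2.10 to 3.31), and Plaur 2.59 higher (1.92 to 3.25). Chordc1, a heat shock cofactor, was lower after rivenprost (-1.08, SE 0.18, adjusted p = 0.00489), as was Rbm39 (-0.94, adjusted p = 0.00437), whose call ended in a fit of these 2 groups alone (adjusted p = 0.0635). In all 45 genes differed between rivenprost and sulprostone, 40 higher and 5 lower. The count was 27 without rivenprost replicate 1 or sulprostone replicate 2, 29 without rivenprost replicate 2 or sulprostone replicate 3, 21 without rivenprost replicate 3 or 4, and 24 without sulprostone replicate 4. Compared with sulprostone alone, the 2 agonists together held Socs3 higher by 3.72, Fos by 3.11, Plaur by 2.94 and Rasd1 by 2.63, and Dnajb1, a heat shock gene, lower (-0.93, SE 0.14, adjusted p = 0.003). These were among 33 genes, 27 higher and 6 lower. That count was 20 without sulprostone replicate 2 or replicate 2 or 3 of both agonists, 17 without sulprostone replicate 3, 21 without replicate 4 of both agonists, and 16 in a fit of these 2 groups alone.

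Between both agonists and rivenprost alone in HSC edgeR called 0 genes (372 at an unadjusted p under 0.05, 63 by DESeq2). The difference was -0.11 for Crem (95% interval -0.68 to 0.45), -0.03 for Hk2 (-0.45 to 0.39) and 0.36 for Plaur (-0.27 to 0.98). For Fos it was 2.09 (1.13 to 3.04), for Jun -1.23 (-1.78 to -0.67) and for Txnip -0.90 (-1.30 to -0.49), each with adjusted p = 0.88. Misoprostol against both agonists also gave 0 genes by edgeR (519 unadjusted, 111 by DESeq2), with -1.18 for Crem (-1.75 to -0.60), -1.17 for Plaur (-1.80 to -0.54) and -0.22 for Hk2 (-0.64 to 0.20). Departure from additivity of the 2 agonists on the log scale gave 0 genes (497 unadjusted, 102 by DESeq2), with Crem at -2.22 (-3.03 to -1.4, adjusted p = 0.1) and Nr4a1 at -1.79 (-2.88 to -0.70). It gave 1 gene without vehicle replicate 1 or vehicle replicate 4. The intervals had a median reach of 0.65 log2 units on either side over genes of at least 5 CPM.

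In the stroma, the effect of irradiation was read from vehicle mice. Mdm2, the ubiquitin ligase that acts on p53 (chromosome 10, 117688875 to 117710758), rose from 57.1 ± 4.73 CPM without to 196 ± 11.8 CPM with irradiation (log2 fold change 1.78, SE 0.17, adjusted p = 2.55e-07). Cdkn1a, the cell cycle inhibitor p21 (chromosome 17, 29090986 to 29100722), rose from 35.1 ± 7.39 to 316 ± 64.6 CPM (3.17, SE 0.32, adjusted p = 5e-07), and Sesn2 (chromosome 4, 132492807 to 132510456) from 18.1 ± 1.65 to 121.6 ± 16.1 CPM (2.75, SE 0.25, adjusted p = 1.37e-07). The death receptor gene Tnfrsf10b (3.95), Eda2r (3.97), the apoptosis genes Bbc3 (2.63) and Pmaip1 (2.71), Plk2 (3.06), Ddit4 (2.25) and the thiamine transporter gene Slc19a2 (3.24) rose too. Fam212b (4.33), the ligand gene Tnfsf4 (5.01), its family's receptor gene Cd40 (3.41), and the NF-kB genes Nfkbia (1.88) and Relb (1.72) also rose, while Hyls1 fell by 1.48. Of 45 p53 targets 24 rose (30 rose and 1 fell adjusted over the list alone), with a median of 0.88 and adjusted p = 0.00016 with an estimated correlation. Of 37 NF-kB and inflammatory cytokine genes 7 rose (13 adjusted over the list alone, median 0.74, adjusted p = 0.061 with an estimated correlation), and of 31 immediate early genes 3 rose (15 rose and 1 fell adjusted over the list alone, median 0.89, adjusted p = 0.16 with an estimated correlation). None of the 37 cAMP-CREB response genes passed, but the list leaned upward (median at least 0.27). Irradiation raised 100 genes and lowered 17, and the count of both was 69 without non-irradiated vehicle replicate 4 and 58 in a fit of these 2 groups alone. Mesenchymal CAR-cell and osteoblast-lineage markers had medians of -0.56 and -0.60 (adjusted p = 0.6 and 0.86 with an estimated correlation), with 0 members called in either list.

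Next, dmPGE2 was compared with vehicle in the stroma of non-irradiated mice. The nuclear receptor genes Nr4a3 (chromosome 4, 48045305 to 48086446) and Nr4a1 rose from 8.89 ± 6.48 to 309 ± 77.7 CPM (log2 fold change 5.33, SE 0.67, adjusted p = 3.18e-05) and from 23.1 ± 8.66 to 429 ± 199 CPM (4.32, SE 0.50, adjusted p = 1.12e-05). The stress gene Ddit4 (3.18), Apold1 (4.17), Rasd1 (3.91), Gprc5a (4.69), Fosl2 (2.72) and Maff (2.73) rose as well. Among cytokine genes, Tnfsf11, which encodes the osteoclast differentiation factor RANKL (chromosome 14, 78277446 to 78308043), rose from 40.7 ± 27.7 to 331 ± 89.6 CPM (3.04, SE 0.53, adjusted p = 0.00108). Il6 rose from 7.99 ± 5.42 to 70.6 ± 30.8 CPM (3.51), Lif from 2.86 ± 1.31 to 61.2 ± 26.0 CPM (4.69), and Cxcl1 by 4.13. The hormone gene Fgf23 (4.32) and Vegfa (2.66) rose, and the endothelial transcription factor gene Sox18 (-2.35) and the interferon-inducible gene Irgm2 (-1.89) fell. Snai2, a transcription factor gene, fell by 2.88 (adjusted p = 0.00155), and was at -2.92 but not called in a fit of these 2 groups alone (adjusted p = 0.0945). Cdkn1a rose to 172 ± 50.4 CPM (2.28, SE 0.31, adjusted p = 8.04e-05), and Mdm2 stood at 55.6 ± 5.41 CPM.

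In that comparison 17 of 37 cAMP-CREB response genes rose (24 rose and 1 fell adjusted over the list alone), with a median of 1.55 and adjusted p = 0.0036 with an estimated correlation. Of 31 immediate early genes 8 rose (17 adjusted over the list alone, median 0.94), and of 27 glucocorticoid response genes 8 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.60), each with adjusted p = 0.084 with an estimated correlation. Of 37 NF-kB and inflammatory cytokine genes 6 rose (9 adjusted over the list alone, median 0.24, adjusted p = 0.48 with an estimated correlation). Of the p53 targets 5 rose and 2 fell (6 and 2 adjusted over the list alone, median 0.11, adjusted p = 0.78 with an estimated correlation). Erythroid and endothelial markers had medians of 0.67 and 0.47, and osteoblast-lineage markers -0.53 (adjusted p = 0.67, 0.78 and 0.78 with an estimated correlation). A total of 570 genes changed, 268 rising and 302 falling, of which 231 were called with each library left out in turn. The count was 370 without non-irradiated dmPGE2 replicate 1, 364 and 293 without non-irradiated vehicle replicate 2 and 3, 334 without the later-numbered replicate 4 of both groups, which stood apart on the first principal component, and 85 in a fit of these 2 groups alone.

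In irradiated mice dmPGE2 changed 300 stroma genes, and several p53 targets were lower than in irradiated vehicle mice. Mdm2 stood at 83.8 ± 10.3 against 196 ± 11.8 CPM (log2 fold change -1.23, SE 0.17, adjusted p = 0.000463), Sesn2 at 40.5 ± 5.61 against 121.6 ± 16.1 CPM (-1.59, SE 0.24, adjusted p = 0.000722) and Ccng1 at 209 against 485 CPM (-1.21, SE 0.20, adjusted p = 0.00163). Eda2r fell by 2.05 and Snai2 by 2.73. The protease gene Adamts1 (chromosome 16, 85793828 to 85803115) rose from 81.2 ± 32.5 to 836 ± 427 CPM (3.35, SE 0.47, adjusted p = 0.000463), and Nr4a3 from 11.3 ± 4.32 to 214.3 ± 113.2 CPM (4.15, SE 0.63, adjusted p = 0.000722). Nr4a1 (2.81), the potassium channel subunit gene Kcne4 (4.98), Gprc5a (3.79), Lif (3.43), Fosl2 (1.70) and Per1 (1.14) rose, as did Tnfsf11, from 39.6 ± 15.5 to 248.6 ± 130.5 CPM (2.68, SE 0.52, adjusted p = 0.00458). Phlda3 (-2.07) and Adamts4 (3.18) passed the test (adjusted p = 0.00458 and 0.00889), and not in a fit of these 2 groups alone (adjusted p = 0.0521 and 0.0523).

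Of the 45 p53 targets 0 rose and 14 fell after dmPGE2 in irradiated stroma (1 and 21 adjusted over the list alone), with a median of -0.37 and adjusted p = 0.068 with an estimated correlation. Of 37 cAMP-CREB response genes 12 rose (17 rose and 1 fell adjusted over the list alone, median 0.67, adjusted p = 0.068 with an estimated correlation). Of 31 immediate early genes 6 rose (8 adjusted over the list alone, median 0.42, adjusted p = 0.73 with an estimated correlation). Of 32 niche factor genes 3 rose and 1 fell, over all genes and over the list alone (median -0.29, adjusted p = 0.89 with an estimated correlation), and Lif and Tnfsf11 were among those that rose. Of 36 mitotic genes 1 rose (18 adjusted over the list alone, median 0.46, adjusted p = 0.57 with an estimated correlation). Granulocyte, monocyte and osteoblast-lineage markers had medians of -0.36, -0.41 and -0.72, and erythroid markers 0.37 (adjusted p = 0.81, 0.57, 0.81 and 0.81 with an estimated correlation). Of the 300 genes 169 fell and the others rose, and 97 of them were called with each library left out in turn. The count was 172 without dmPGE2 replicate 2, 174 without vehicle replicate 3, 41.7% of the 300 without dmPGE2 replicate 1, 43% without vehicle replicate 2, and 198 in a fit of these 2 groups alone.

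Whether the response to dmPGE2 differed with irradiation was tested as an interaction, which 4 genes passed, all with a lower log2 fold change for dmPGE2 in irradiated than in non-irradiated stroma, with 379 genes at an unadjusted p under 0.05 and 15 called by DESeq2. Cdkn1a stood at 35.1 ± 7.39 CPM without and 172 ± 50.4 CPM with dmPGE2 in non-irradiated stroma, and at 316 ± 64.6 and 227 ± 90.5 CPM in irradiated stroma (difference of log2 fold changes -2.75, SE 0.43, adjusted p = 0.00565). The same 4 means for Ddit4 were 30.8 ± 6.65, 275 ± 87, 146 ± 10.3 and 245 ± 84.4 CPM (-2.43, SE 0.37, adjusted p = 0.00565), and for Tnfrsf10b 1.70 ± 0.605, 4.42 ± 1.56, 26.7 ± 8.70 and 8.0 ± 3.8 CPM (-3.10, SE 0.51, adjusted p = 0.00944). The fourth gene was Sesn2, at 18.1 ± 1.65, 22.7 ± 4.11, 121.6 ± 16.1 and 40.5 ± 5.61 CPM (-1.91, SE 0.34, adjusted p = 0.0207), a call that ended without any 1 of 11 single libraries (highest adjusted p = 0.092) and without replicate 4 of both non-irradiated groups (adjusted p = 0.159). Of the 45 p53 targets 3 passed with a negative difference (15 adjusted over the list alone), and the median difference was -0.61 (adjusted p = 0.00087 with an estimated correlation). Other groupings of the same libraries could not decide whether chance gave this count, as the closing section sets out, and chance is not excluded for it.

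**Figure D3:**
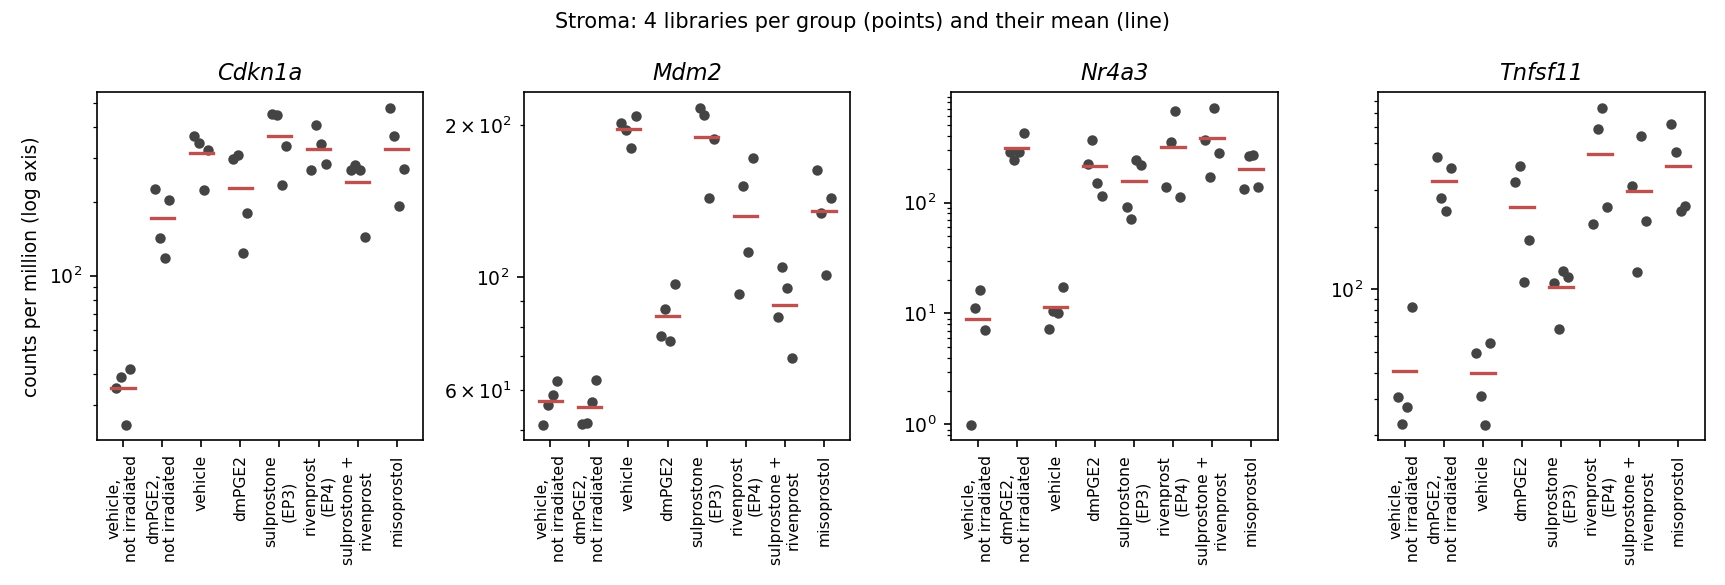
Expression of Cdkn1a, Mdm2, Nr4a3 and Tnfsf11 in each stroma library (CPM, log axis) for the 8 groups, with 1 point per mouse and the group mean. Mdm2 averaged 57.1 CPM in non-irradiated vehicle, 196 in irradiated vehicle and 83.8 in irradiated dmPGE2 stroma.

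**Figure D4:**
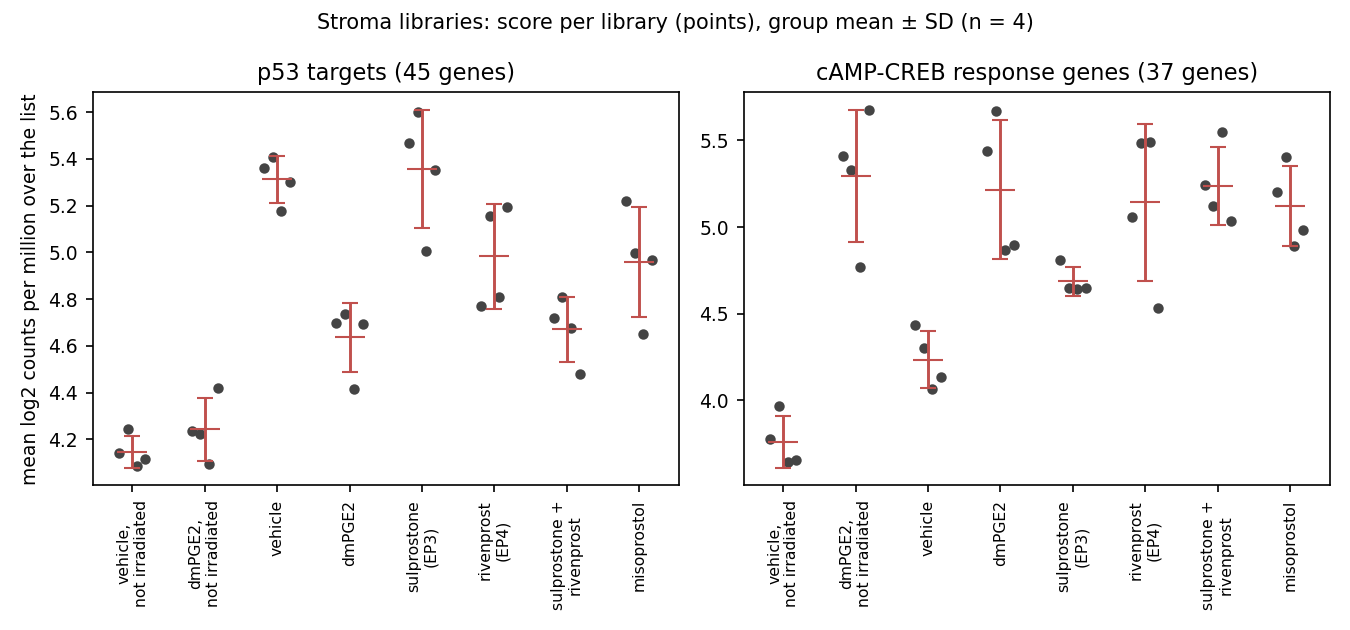
Mean log2 CPM of the p53 targets and of the cAMP-CREB response genes in each stroma library for the 8 groups, with the group mean ± SD of 4 mice. The median log2 fold change of the p53 targets was 0.88 for irradiation and -0.37 for dmPGE2 in irradiated mice.

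Sulprostone in irradiated stroma raised 15 genes and lowered 1. Akap12, an anchoring protein of protein kinase A, rose from 80.5 ± 16.7 to 297 ± 28.6 CPM (log2 fold change 1.88, SE 0.25, adjusted p = 0.000555). Ptx3, a pentraxin of innate immunity, rose from 18.8 ± 7.03 to 221 ± 81.7 CPM (3.56, SE 0.53, adjusted p = 0.00264). Of the cAMP-CREB response genes 1 of 37 rose (3 rose and 1 fell adjusted over the list alone, median 0.43, adjusted p = 0.43 with an estimated correlation). Of the immediate early genes 2 of 31 rose (5 adjusted over the list alone, median 0.31, adjusted p = 0.58 with an estimated correlation), and of the p53 targets 0 of 45. Granulocyte markers had a median of -0.69 (adjusted p = 0.86 with an estimated correlation). The gene that fell was Tusc5 (-2.05, adjusted p = 0.0191), whose call ended without sulprostone replicate 1, 2, 3 or 4 (adjusted p = 0.0899, 0.0618, 0.0592 and 0.0865) and without vehicle replicate 2 or 3 (0.111 and 0.0664). The count of 16 was 7 without vehicle replicate 1 or 4 or sulprostone replicate 1, 9 and 4 without vehicle replicate 2 and 3, and 10, 5 and 6 without sulprostone replicate 2, 3 and 4, and it was 9 under a stricter filter on low counts.

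Rivenprost changed 172 genes of irradiated stroma, 35 of them falling. Adamts1 (log2 fold change 3.78, SE 0.48, adjusted p = 0.000119), Nr4a3 at 319 ± 260 CPM (4.58, SE 0.64, adjusted p = 0.000397), Tnfsf11 at 445 ± 260 CPM (3.57, SE 0.54, adjusted p = 0.000652) and Thbd, the thrombomodulin gene, at 1033 ± 865 CPM against 65.4 ± 18.3 (3.65, SE 0.53, adjusted p = 0.000524) rose. Adamts4 (4.79), Gprc5a (4.19), Kcne4 (4.42), Il6 (3.49), Tnfaip6 (3.05), Crem (1.92), Irs2 (1.84) and Pde4d (1.4) rose too, and Banp fell from 30.3 to 10.7 CPM (-1.51, SE 0.23, adjusted p = 0.000649). Of the genes named here Banp alone was also called in a fit of these 2 groups alone, which called 2 genes and gave the others adjusted p from 0.0684 to 0.202. Of 37 cAMP-CREB response genes 13 rose (17 adjusted over the list alone, median 0.67, adjusted p = 0.085 with an estimated correlation). Of 31 immediate early genes 5 rose (6 adjusted over the list alone, median 0.33, adjusted p = 0.78 with an estimated correlation), and of 45 p53 targets 0 (median -0.23, adjusted p = 0.33 with an estimated correlation). Granulocyte, monocyte and osteoblast-lineage markers had medians of -0.78, -0.38 and -0.66 (adjusted p = 0.79, 0.53 and 0.79 with an estimated correlation). The count was 94, 81 and 56 without vehicle replicate 1, 2 and 3, and 95 and 49 without rivenprost replicate 2 and 3.

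Both agonists together changed 469 genes of irradiated stroma, 227 rising and 242 falling. Mdm2 stood at 88.3 ± 15.4 CPM (log2 fold change -1.15, SE 0.17, adjusted p = 0.000359) and Sesn2 at 42.7 ± 9.0 CPM (-1.51, SE 0.24, adjusted p = 0.000713), and Polk, a DNA polymerase of lesion bypass, fell by 1.67 (SE 0.32, adjusted p = 0.00295). Adamts1 (3.73), Nr4a3 (5.0, at 382 ± 236 CPM), Kcne4 (4.89), Gprc5a (3.89), Lif (3.48), Il6 (3.46), Tnfsf11 (2.95, at 297 ± 182 CPM), Nr4a1 (2.83) and Tnfaip6 (2.60) rose. Snai2 (-3.11), Tusc5 (-2.66), Irgm2 (-2.04) and the repressor gene Bcl6 (-1.49) fell. Of the p53 targets 0 of 45 rose and 14 fell (20 adjusted over the list alone, median -0.50, adjusted p = 0.12 with an estimated correlation). Of 37 cAMP-CREB response genes 15 rose (18 rose and 2 fell adjusted over the list alone, median 0.60, adjusted p = 0.12 with an estimated correlation), and of 34 interferon-stimulated genes 2 fell (7 adjusted over the list alone, median -0.50, adjusted p = 0.29 with an estimated correlation). Granulocyte, monocyte and osteoblast-lineage markers had medians of -1.02, -0.60 and -0.77 (adjusted p = 0.8, 0.53 and 0.8 with an estimated correlation). The count was 206, 264 and 247 without replicate 1, 2 and 4 of both agonists, 215 and 233 without vehicle replicate 2 and 3, 736 without replicate 4 of both non-irradiated groups and 255 in a fit of these 2 groups alone.

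Misoprostol raised 103 genes of irradiated stroma and lowered 36. Adamts1 (log2 fold change 3.65, SE 0.47, adjusted p = 0.000173), Crem (2.08, SE 0.29, adjusted p = 0.000318), Nr4a3 at 200 ± 74.7 CPM (4.01, SE 0.62, adjusted p = 0.00141) and Tnfsf11 at 391 ± 183 CPM (3.32, SE 0.53, adjusted p = 0.00189) rose. Adamts4 (4.71), Kcne4 (4.17), Fgf23 (4.06) and Gprc5a (3.50) rose too, and Banp fell by 1.13. Il6 (3.84, adjusted p = 0.00332) was not called in a fit of these 2 groups alone (adjusted p = 0.0633). Of 37 cAMP-CREB response genes 11 rose (17 rose and 1 fell adjusted over the list alone, median 0.48, adjusted p = 0.13 with an estimated correlation). Of 31 immediate early genes 5 rose (10 rose and 1 fell adjusted over the list alone, median 0.32, adjusted p = 0.44 with an estimated correlation), and of 45 p53 targets 0 passed the test (median -0.25, adjusted p = 0.29 with an estimated correlation). Granulocyte markers had a median of -1.19, with 1 of 25 falling (3 adjusted over the list alone, adjusted p = 0.44 with an estimated correlation), and monocyte markers a median of -0.58 (adjusted p = 0.33 with an estimated correlation). The count of both directions was 71 and 55 without misoprostol replicate 1 and 2, 78, 48 and 87 without vehicle replicate 2, 3 and 4, and 67 in a fit of these 2 groups alone.

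Compounds were compared with dmPGE2 directly in irradiated stroma. Mdm2 was 1.17 log2 units higher after sulprostone than after dmPGE2 (95% interval 0.83 to 1.52), Sesn2 1.4 higher (0.91 to 1.90) and Nr4a1 lower (-1.92, -2.85 to -1.0), with adjusted p = 0.0013, 0.0057 and 0.03. None of these 3 was called in a fit of these 2 groups alone. Mdm2 and Sesn2 stayed called with each library left out in turn, and the call of Nr4a1 ended without any 1 of 6 single libraries (highest adjusted p = 0.145). In all 194 genes differed, 160 higher and 34 lower after sulprostone, and 11 of them were called with each library left out in turn. That count was 22, 96, 40 and 96 without dmPGE2 replicate 1, 2, 3 and 4, 37, 11, 762 and 80 without sulprostone replicate 1, 2, 3 and 4, 431 without replicate 4 of both non-irradiated groups, and 1 in a fit of these 2 groups alone. It was far higher with the run of animal numbers as a block. Rivenprost against dmPGE2 gave 0 genes by edgeR (1468 at an unadjusted p under 0.05, 18 by DESeq2) and 49 without rivenprost replicate 1. The difference was 0.66 for Mdm2 (0.32 to 1.00, adjusted p = 0.39), 0.97 for Sesn2 (0.48 to 1.45), 0.44 for Nr4a3 (-0.70 to 1.57) and 0.89 for Tnfsf11 (-0.12 to 1.90). Both agonists against dmPGE2 gave 0 genes (96 unadjusted, 0 by DESeq2), with 0.08 for Mdm2 (-0.26 to 0.42), 0.08 for Sesn2 (-0.41 to 0.56), 0.85 for Nr4a3 (-0.28 to 1.98) and 0.27 for Tnfsf11 (-0.73 to 1.27). Misoprostol against dmPGE2 gave 0 genes (726 unadjusted, 4 by DESeq2) and 1 without misoprostol replicate 3, with 0.69 for Mdm2 (0.35 to 1.03, adjusted p = 0.79), 1.00 for Sesn2 (0.51 to 1.49) and -0.14 for Nr4a3 (-1.26 to 0.99).

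Among the agonists in irradiated stroma, Rnf125 was higher (1.20, SE 0.16, adjusted p = 0.000932) and Pdlim5 lower (-0.88, SE 0.12, adjusted p = 0.0012) after rivenprost than after sulprostone, and in a fit of these 2 groups alone they were at 1.18 and -0.89 and not called (adjusted p = 0.202 and 0.33). They were among 5 genes, 2 higher and 3 lower, or 7 higher and 3 lower with RLE size factors. The others were Banp (-1.39, adjusted p = 0.00932), Pde4d (1.01, adjusted p = 0.0178) and Uhrf2 (-0.56, adjusted p = 0.0417). The call of Banp ended without sulprostone replicate 2 (0.121) or rivenprost replicate 3 (0.117). That of Pde4d ended without replicate 1 or 2 of sulprostone (0.13 and 0.176) or 2 or 3 of rivenprost (0.0597 and 0.124). That of Uhrf2 ended without replicate 1, 2 or 4 of sulprostone (0.218, 0.289 and 0.0737) or 1, 2 or 3 of rivenprost (0.0608, 0.0597 and 0.177). The count was 3 without sulprostone replicate 1 or rivenprost replicate 2, 2 without sulprostone replicate 2 or rivenprost replicate 3, 64 without sulprostone replicate 3, 23 without rivenprost replicate 4, 10 under a stricter filter, 1.4e+02 by DESeq2 and 0 in a fit of these 2 groups alone. Both agonists against sulprostone alone gave 254 genes, 57 higher and 197 lower, with Polk lower (-1.86, SE 0.32, adjusted p = 0.00429), as were Luc7l3 (-1.90) and Snai2 (-2.77), both of which were not called in a fit of these 2 groups alone (adjusted p = 0.098 and 0.0687). That count was 60, 28, 616 and 103 without sulprostone replicate 1, 2, 3 and 4, 34 and 40 without replicate 1 and 4 of both agonists, 46.5% and 54.7% of the 254 without their replicate 2 and 3. It was 520 without replicate 4 of both non-irradiated groups, and 2 in a fit of these 2 groups alone. Both agonists against rivenprost gave 0 genes by edgeR (765 unadjusted, 0 by DESeq2) and 1 without rivenprost replicate 1, with Mdm2 at -0.58 (95% interval -0.92 to -0.24, adjusted p = 0.88). Misoprostol against both agonists gave 0 genes (469 unadjusted, 1 by DESeq2), with Mdm2 at 0.61 (0.27 to 0.95, adjusted p = 0.93) and Akap12 at 1.14 (0.64 to 1.64). Departure from additivity of the 2 agonists gave 0 genes (655 unadjusted, 15 by DESeq2), with Nr4a3 at -3.34 (-4.98 to -1.69, adjusted p = 0.43) and Akap12 at -1.70 (-2.39 to -1.0, adjusted p = 0.13). It gave 1 gene without sulprostone replicate 1, 6 without rivenprost replicate 1 and 1 without replicate 3 of both agonists. The intervals had a median reach of 0.35 log2 units on either side over genes of at least 5 CPM.

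Comparisons that share the irradiated vehicle libraries were set against each other with the part that shared controls add. Over 16 pairs of such comparisons the correlation of log2 fold changes across genes ran from 0.355 to 0.855 (median 0.590), against 0.456 to 0.533 over the simulations of groups without any effect, and the median was 0.120 with the vehicle libraries split between the 2 comparisons. Genes are not independent replicates, so these correlations carry no p. The covariance in HSC was 0.631 between rivenprost and both agonists against 0.340 simulated, a difference of 0.291. In stroma it was 0.215 between dmPGE2 and both agonists against 0.0675 simulated (difference 0.147), 0.177 between rivenprost and misoprostol against 0.0675 (0.11), and 0.0683 between dmPGE2 and sulprostone against 0.0676 (0.000743). In HSC 42 genes rose and 4 fell with both rivenprost and the 2 agonists together, where independent lists of these sizes would share 0.219 and 0.0182. In stroma 104 genes rose and 1.3e+02 fell with both dmPGE2 and the 2 agonists together (1.96 and 2.7 for independent lists), and 70 rose and 20 fell with both dmPGE2 and rivenprost (1.18 and 0.390). Unchanged groups held calls in only 10 of 100 simulations, so 0 shared calls decide nothing. With the vehicle libraries split between the 2 comparisons, the same overlaps averaged 20.75 rising and 1 falling in HSC, and in stroma 11.75 rising and 21 falling for dmPGE2 and the 2 agonists, and 5 rising and 1.25 falling for dmPGE2 and rivenprost. Each comparison then rests on 2 vehicle libraries, which also lowers its own calls.

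Comparisons without shared libraries were also set side by side. Among 12991 genes tested in both cell fractions, 14 rose after rivenprost in HSC and in stroma (0.474 for independent lists), 16 rose and 7 fell after both agonists (0.868 and 0.302), 10 rose after misoprostol (0.187), and 0 rose after sulprostone, which had 2 rising genes in HSC and 9 in stroma among them. For dmPGE2 in stroma, 89 genes rose both with and without irradiation (2.31 for independent lists) and 79 fell in both. The log2 fold changes of these 2 comparisons correlated at 0.630 across genes. Between HSC and stroma they correlated at 0.093 for rivenprost, 0.097 for both agonists, 0.075 for misoprostol and -0.047 for sulprostone.

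The authors' deposited table gives their own calls, counted here where their false discovery rate was under 0.05. In HSC it holds 8 rising and 1 falling gene for sulprostone, 86 and 26 for rivenprost, 88 and 40 for both agonists and 47 and 19 for misoprostol, and 2, 66, 74 and 34 genes were called both in the authors' deposited table and here. For stroma the authors' deposited table holds 157 genes for irradiation, 31 of them falling, 288 and 300 for dmPGE2 without irradiation, 179 and 210 for dmPGE2 with irradiation, 26 and 4 for sulprostone, 184 and 51 for rivenprost, 259 and 272 for both agonists and 145 and 85 for misoprostol. Of these, 519, 284, 16, 165 and 431 genes were called here as well for dmPGE2 without and with irradiation, sulprostone, rivenprost and both agonists. Between compounds in HSC, the authors' deposited table holds 103 genes for rivenprost against sulprostone (45 here) and 105 for both agonists against sulprostone (33 here), and it includes all of those called here. In stroma it holds 322 for sulprostone against dmPGE2 (194 here, 190 in both), 63 for rivenprost against sulprostone (5 here, 5 in both) and 327 for both agonists against sulprostone (254 here, 244 in both). The other direct comparisons hold 0 genes here and 0 or 1 in the authors' deposited table. Across genes, log2 fold changes from the authors' deposited table and from the present fit correlated at 0.941 to 0.968 in HSC and at 0.985 to 0.995 in stroma.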

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

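Of the tests here, those on RNA of other blood cells, on a response to the EP3 agonist, on low depth, on the later-numbered non-irradiated pair and on a male under a female label were chosen only after the result was seen. A library is listed below where the gap between it and the nearest library of its group, divided by the range of the 4 libraries of that group, lay above Dixon's 95% critical value. Chance alone marks about 1 in 20 groups in this way. Here 25 of 455 combinations of a library measure with a group and 16 of 377 combinations of a gene with a group were marked, close to that rate, so most single entries call for no explanation.

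In HSC, sulprostone replicate 1 stood apart in the share of the gene with most counts (ratio 0.979) and in monocyte and macrophage (0.87), mast cell and basophil (0.92) and osteoblast-lineage markers (0.842). Sulprostone replicate 4 did so in endothelial markers (0.864). Vehicle replicate 2 stood apart in NF-kB and inflammatory cytokine genes (0.894), misoprostol replicate 2 in p53 targets (0.847) and erythroid markers (0.858), and rivenprost replicate 3 in p53 targets (0.897) and replicate 1 in heat shock genes (0.85). After both agonists, replicate 4 stood apart in hypoxia response genes (0.83) and replicate 1 in T and NK cell markers (0.956). Among single genes these were Pdcd1 in vehicle replicate 1 and Ramp3 in sulprostone replicate 1 (each 1, as the other 3 libraries were equal), and Rsrp1 in replicate 4 (0.838) and Sgk1 in replicate 2 (0.964) of both agonists.

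In irradiated stroma, vehicle replicate 4 stood apart in B-cell markers (0.832), dmPGE2 replicate 3 in p53 targets (0.869) and Wnt target genes (0.839), and sulprostone replicate 1 in cAMP-CREB response genes (0.965). Replicate 2 of both agonists did so in prostaglandin receptor and metabolism genes (0.882), Wnt target genes (0.939), pericyte and smooth muscle markers (0.876) and fibroblast and chondrocyte markers (0.86). Misoprostol replicate 3 stood apart in mitotic genes (0.957), endothelial markers (0.895) and erythroid markers (0.856). Without irradiation, vehicle replicate 4 stood apart in hypoxia response genes (0.866) and NRF2 antioxidant genes (0.856).

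Single genes in stroma were Phlda3 (0.865) and Sox18 (0.911) in dmPGE2 replicate 3, Snai2 in dmPGE2 replicate 4 (0.866), Socs3 in vehicle replicate 2 (0.849), Nr4a1 in sulprostone replicate 3 (0.965) and Fgf23 in misoprostol replicate 3 (0.895). With both agonists they were Nr4a2 in replicate 2 (0.915), and Lif (0.88) and Per1 (0.971) in replicate 3. Without irradiation they were Bhlhe40 in vehicle replicate 4 (0.854), Eda2r in vehicle replicate 2 (0.837) and Fosl2 in dmPGE2 replicate 4 (0.86). For 4 genes the effect of dmPGE2 in stroma differed with irradiation by the interaction test, Tnfrsf10b (-3.10), Cdkn1a (-2.75), Ddit4 (-2.43) and Sesn2 (-1.91).

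Sulprostone replicate 1 of HSC held markers of several mature blood cells, with scores (mean log2 CPM) of 7.64 for granulocyte markers against -0.38 to 2.63 in the other 19 HSC libraries and 5.16 for B-cell markers against -2.03 to 0.9, and an HSC marker score of 5.79 against 6.16 to 6.62. A response to the EP3 agonist is argued against, since the granulocyte score of the other 3 sulprostone libraries averaged 1.08 (SD 1.18), within the 0.24 to 2.63 of vehicle, and low depth is argued against by sulprostone replicate 4, of like depth, at 0.32. RNA of other blood cells may be the source, because 92.3% of the measured granulocyte, monocyte, erythroid and B-cell markers, 72 of 78, were highest in this library. The most abundant, chosen after their values were seen, were Car2 (5100 CPM against at most 3120 in another library), S100a8 (3780 against 41.9), Alas2 (3640 against 231) and Lyz2 (3540 against 725). The sort for stem cells should remove such cells, and whether whole cells or free RNA carried the signal is open.

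The second pattern was that p53 targets responded to dmPGE2 differently with and without irradiation in stroma, by -0.77 (SE 0.17) in their mean log2 CPM. A shift in cell types as the whole cause is argued against by -0.69 (SE 0.17) with 5 marker scores as covariates, and depth with the share of the top gene by -0.72 (SE 0.12). Without the later-numbered replicate 4 of both non-irradiated groups it was -0.70 (SE 0.19), which argues against that pair as the whole cause. The count of 4 genes past the interaction test was reached by 13 of 100 groupings of the same libraries. These shuffled the labels of all groups of the test within each sex. Effects of dmPGE2 or irradiation alone can then enter the interaction, so the groupings cannot decide on chance. Chance is not excluded for that count. The cause of the pattern stays open.

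The third pattern was a low count of Xist in non-irradiated vehicle replicate 4 of stroma, 161 against 5524 to 19965 in the other 15 female and at most 17 in the male stroma libraries. A male sample under a female label is argued against by the 4 Y-linked genes, which summed to 0 counts against 7329 to 16662 in males. A single X chromosome, or loss of a copy of it in most cells, may be the cause, as the mean log2 CPM of 6 genes that escape X inactivation was 6.76, below the 7.34 to 7.73 of the other females. It was also below the 6.90 to 7.4 of males, which a single X alone would not give, so part of the difference stays open. No biological explanation tied to the treatments was tested, and without this library irradiation changed 69 genes.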

How the results depend on the processing

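Fits with the position in the number run, without the HSC libraries that stood apart, without the later-numbered non-irradiated pair, the leave-one-out fits of the sex difference and the split of vehicle libraries for shared calls were chosen only after the data were seen. Counts below are of genes at an adjusted p under 0.05, and where an alternative moved one the cause was not tested unless given. Of the 318 pairs of a gene and a comparison, no log2 fold change reversed under any of the alternatives. Over 5260 such values 4561 stayed on the same side of the threshold, 665 lost the call and 34 gained it. Leaving out single libraries accounted for 491 of the losses among 2624 values, and fits of only the groups compared for most of the others. RLE size factors ended 1 call, the stricter filter 3, no sex term 14, the run as a replicate block 3 (and 1 gained), the fit without the apart HSC libraries 13 and that without the later pair 15. The fit with no filter is void, as the filter removed 0 genes.

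DESeq2 called more genes than edgeR. Its counts in HSC were 103 for sulprostone (2 by edgeR), 234 for rivenprost (67), 301 for both agonists (74) and 235 for misoprostol (34). Between treatments they were 172 for rivenprost against sulprostone, 227 for both agonists against sulprostone, 63 for both against rivenprost, 111 for misoprostol against both, and 102 for additivity. In stroma they were 248 for irradiation, 969 for dmPGE2 without and 670 with irradiation, 38 for sulprostone, 347 for rivenprost, 883 for both agonists and 378 for misoprostol. Against dmPGE2 they were 654 for sulprostone, 18 for rivenprost and 4 for misoprostol. Against sulprostone they were 1.4e+02 for rivenprost and 633 for both agonists. Misoprostol against both gave 1, additivity 15 and the interaction of dmPGE2 with irradiation 15. The sex difference of the comparisons with a control gave 0 genes by edgeR and 247 over all of them by DESeq2, with 299 to 505 at an unadjusted p under 0.05 in HSC and 91 to 267 in stroma.

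A fit of only the groups compared has fewer libraries to estimate the spread from. It gave 0 genes for sulprostone, 43 for both agonists, 9 for misoprostol and 16 for both against sulprostone in HSC. In stroma it gave 58 for irradiation, 85 for dmPGE2 without and 198 with irradiation, 2 for rivenprost, 255 for both agonists and 67 for misoprostol, and 1 for sulprostone against dmPGE2, 0 for rivenprost against sulprostone and 2 for both against sulprostone. With a log2 fold change of at least 1 demanded as well, counts in stroma were 75 for irradiation, 239 for dmPGE2 without and 1.4e+02 with irradiation, 94 for rivenprost and 210 for both agonists. RLE size factors gave 10 genes for rivenprost against sulprostone in stroma, the stricter filter 10 for the same comparison and 9 for sulprostone. Scaling moved no other count by over 1.5 times.

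Animals fell into runs of consecutive numbers that hold 1 animal of each group and that match the replicate numbers, apart from replicate 4 of both non-irradiated groups, which were numbered later. The labels do not say that a run is a day or a batch. Deviations from group means correlated within a run at 0.207 to 0.602 on average in stroma, against 0.0408 for the same sex in different runs and -0.135 between sexes, and at 0.0221 to 0.0468 in HSC, against -0.00495 and -0.0139. Single pairs within a run went down to -0.239 in stroma and -0.0611 in HSC. As not every pair passed 0.1 the animals were not paired by run. The stroma spread in the main model thus includes differences between runs of a sex. In stroma 31 of 32 and in HSC 9 of 20 libraries lay closest to a library of their own run. With the run as a replicate block in place of sex, stroma counts were 241 for irradiation, 1431 for dmPGE2 without and 1169 with irradiation, 379 for rivenprost, 1342 for both agonists and 353 for misoprostol. They were 1735 for sulprostone and 1 for rivenprost against dmPGE2, 1.4e+02 for rivenprost and 1442 for both agonists against sulprostone, and 7 for the interaction of dmPGE2 with irradiation. The block moved no HSC count by over 1.5 times and called 301 list tests against 294 without it.

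Without the 3 HSC libraries that stood apart, sulprostone gave 0 genes. With the position in the number run as covariate, both agonists against sulprostone in HSC gave 50. Without the later-numbered pair, stroma counts were 334 for dmPGE2 without irradiation, 736 for both agonists, 431 for sulprostone against dmPGE2 and 520 for both agonists against sulprostone. An estimated correlation between genes left 19 of the list tests. Splitting the vehicle libraries lowered the median correlation of fold changes between comparisons with shared controls from 0.590 to 0.120.

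Each library was left out in turn. In HSC the counts ran from 41 to 70 genes for rivenprost, 49 to 72 for both agonists, 18 to 40 for misoprostol, 21 to 30 for rivenprost and 17 to 38 for both agonists against sulprostone, and 0 to 1 for additivity. In stroma they ran from 69 to 97 for irradiation, 293 to 735 for dmPGE2 without irradiation, 1.3e+02 to 283 with it, 4 to 10 for sulprostone, 49 to 195 for rivenprost, 206 to 396 for both agonists and 48 to 177 for misoprostol. Against dmPGE2 they were 11 to 762 for sulprostone, 0 to 49 for rivenprost and 0 to 1 for misoprostol. Against sulprostone they were 2 to 64 for rivenprost and 28 to 616 for both agonists. Both agonists against rivenprost gave 0 to 1 and additivity 0 to 6. The sex difference gave 0 to 282, with 282 without vehicle replicate 4, 144 and 21 without misoprostol replicate 4 and 3, 39 without sulprostone replicate 3 and 1 without replicate 3 of both agonists, all in HSC.

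In HSC the simulated test recovered 17 of 66 genes changed by 1 on the log2 scale, and in stroma 31 of 66, so changes of this size are often missed at 4 mice per group.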

Other observations

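The genes Tob1 after dmPGE2 and both agonists, Polk after dmPGE2, Parp14, and Vegfa and Sgk1 outside the comparisons where the naming rule allowed them were chosen after their values were seen, and the groupings of libraries for the interactions were extended to 100 after a first result. In irradiated stroma Tob1, an antiproliferative gene, rose by 1.21 on the log2 scale with irradiation (adjusted p = 2.53e-05) and was lower with dmPGE2 (-0.89, adjusted p = 0.00221) and with both agonists (-0.92, adjusted p = 0.00124). Polk was lower with dmPGE2 as well (-1.73, adjusted p = 0.00345). The interferon-stimulated gene Parp14 fell with dmPGE2 (-0.84, adjusted p = 0.00382) and with both agonists (-0.77, adjusted p = 0.00498). Vegfa rose by 2.60 with dmPGE2 (adjusted p = 0.0043) and by 2.64 with both agonists (adjusted p = 0.00286) in irradiated stroma, close to the 2.66 with dmPGE2 in non-irradiated stroma (adjusted p = 0.002). Sgk1 rose by 1.71 in HSC after rivenprost (adjusted p = 0.000519). Each of these calls of edgeR held with each library left out in turn and in a fit of only the groups compared.

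The lists tested gave the following over the 11 comparisons with a control, counting each member once per comparison. Glucocorticoid response genes rose 35 times and fell 5 times (65 adjusted over the list alone, lowest adjusted p = 0.01 with an estimated correlation), hypoxia response genes 21 and 3 (52, 0.027), and niche factor genes 15 and 1 (21, 0.64). HSC quiescence genes rose 13 times and fell 5 (37, 0.11), BCL2-IAP genes 3 and 2 (12, 0.061), Wnt target genes 4 and 2 (10, 0.47), heat shock genes 1 and 3 (15, 0.19) and mitotic genes 2 and 1 (23, 0.57). Interferon-stimulated genes fell 5 times (15, 0.21), and prostaglandin receptor and metabolism genes once (3, 0.43). S-phase genes rose and fell once each (3, 0.64), DNA repair and damage signalling genes rose 1 time and fell 2 times (3, 0.78), NRF2 antioxidant genes fell 1 time (1, 0.79) and lineage-primed progenitor genes 1 time (3, 0.29). HSC markers had 0 calls over all genes (2, 0.82) and cytosolic ribosomal protein genes 0 (0, 0.64).

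For cell-type markers, endothelial genes rose 3 times and fell 3 times (7 adjusted over the list alone, lowest adjusted p = 0.64 with an estimated correlation), pericyte and smooth muscle markers rose 2 times (3, 0.75) and mesenchymal CAR-cell markers fell 2 times (2, 0.6). Plasma cell markers rose 1 time (1, 0.66), B-cell markers fell 1 time (5, 0.61) and granulocyte markers 1 time (6, 0.44). T and NK cell markers rose 5 times (5, 0.61) and mast cell and basophil markers 5 times (5, 0.77), and both lists hold the granzyme gene Gzmb. Osteoblast-lineage (0, 0.64), fibroblast and chondrocyte (2, 0.61), erythroid (7, 0.61), monocyte and macrophage (1, 0.33) and megakaryocyte and platelet markers (0, 0.3) had 0 calls over all genes. These are counts by edgeR.

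Each count of changed genes was set against other groupings of the same libraries, 35 in all for 4 against 4 with the real one included, and 100 for an interaction. No other grouping reached the count in HSC for rivenprost (67 genes, at most 0 in another), both agonists (74, at most 2), misoprostol (34, at most 2), rivenprost against sulprostone (45, at most 1) and both agonists against sulprostone (33, at most 0). In stroma this held for irradiation (100 rising and 17 falling, at most 1), dmPGE2 with irradiation (300, at most 21), sulprostone (16, at most 0), rivenprost (172, at most 1), both agonists (469, at most 0), misoprostol (103 rising and 36 falling, at most 0), sulprostone against dmPGE2 (194, at most 5) and both agonists against sulprostone (254, at most 0). The lowest possible share is 1 in 35, so chance is not excluded over so many comparisons. For sulprostone in HSC the real one led by 1 gene only (2, at most 1), and both calls ended without the 3 libraries that stood apart (adjusted p = 0.0706), so little rests on it.

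For dmPGE2 without irradiation 2 of 35 groupings, the real one included, reached 570 genes, and the other gave 2980. That grouping set replicate 1 of both groups with vehicle replicate 2 and dmPGE2 replicate 3, so the later-numbered replicate 4 of both fell on the same side. This points to a structure of the samples. Groupings that ignore runs cannot decide on chance here. Without this later pair 334 genes differed. Of the 570, 89 rising and 79 falling genes were also called for dmPGE2 in irradiated stroma (2.3 and 3.4 for independent lists). No library is shared, but number runs and the model are, so chance stays open. Nor can chance be excluded for rivenprost against sulprostone in stroma, where 3 of 35 groupings reached 5 genes and the highest other gave 79, again a structure of the samples. In that grouping sulprostone replicate 1, 2 and 4 lay with rivenprost replicate 2. For the interaction of dmPGE2 with irradiation 13 of 100 groupings reached 4 genes, and the highest other gave 3317, which points to a structure of the samples as well.

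Where edgeR called 0 genes every grouping reached the count, 35 of 35 or 100 of 100. The highest other grouping in HSC gave 0 for both agonists against rivenprost (372 genes at an unadjusted p under 0.05, 63 by DESeq2), 3 for misoprostol against both (519, 111) and 1 for additivity (497, 102). In stroma it gave 2 for rivenprost (1468, 18), 0 for both agonists (96, 0) and 0 for misoprostol against dmPGE2 (726, 4), 371 for both agonists against rivenprost (765, 0), 0 for misoprostol against both (469, 1) and 90 for additivity (655, 15). The 371 and the 90 point to a structure of the samples too.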
